A study of Mus musculus with 4 samples.

How the data were processed

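RNA-seq of mouse embryonic fibroblasts was analysed from 3 deposited tables, which compare SKM with empty vector, OSKM with SKM and G3SKM with SKM. Per the labels, the cells were isolated from embryonic skin after removal of the epidermis and cultured in medium with serum, and each of the 4 samples stands for 2 replicates. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase, and amplified cDNA went through further PCR cycles, sonication and a DNA library kit. The submitters' processing notes name TopHat 1.3.0 and the genome build mm9. The read counter, the annotation release and the way the replicates were combined are not given in the sources used here.

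Per the file headers, the authors' deposited values are RPKM, and each table adds the log2 of the ratio of its RPKM columns. The deposited log2 ratio differed from that of the columns by at most 0.0017. The tables list 25509, 25856 and 26364 genes by Ensembl identifier, 27597 in at least 1 table, and the SKM column was identical in all 3 (largest difference 0). A value of 0.001 was read as no reads and set to 0. Symbols, gene spans, exon lengths and transcript GC were taken from GENCODE M21, which covered 25103 (91.0%) of the listed genes. It belongs to a later build than the values, so no coordinates are given, and symbols may differ from those used by the authors.

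The values multiplied by the gene's whole span, introns included, fell on multiples of a single step in each column, within 0.05 of a whole number for 76.5% of genes with 1 to 1000 reads in empty vector, 74.7% in SKM, 75.5% in OSKM and 76.7% in G3SKM, against 10% by chance. The deposited RPKM therefore divide by the gene span, whose median ratio to exon length was 5.50 for protein-coding genes, and genes with long introns have low values. The step gave the depth of each library and the reads per gene, on the assumption that the authors used the spans of GENCODE M21. For genes off whole multiples, Sox2, Klf4, Pou5f1, Slurp1, Krt16 and Sox3 among them, the span may differ, and their reads, intervals and floors are approximate. A single step per column is what pooled reads would give, but how the replicates were combined was not tested. Sums of RPKM are dominated by short genes, and pseudogenes held 56.6% to 58.5% of them.

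No test was possible on 1 value per group. As fixed before the data were examined, a gene was called higher or lower when log2 of the ratio of RPKM + 1 was at least 1 in size, among genes at 1 RPKM or more in at least 1 of the groups compared. The 23 gene lists were fixed in the same way. Their members count as measured once past this filter. A gene can pass it through its higher group alone, so the measured members differ between comparisons. For lists with at least 5 members past the filter, the median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean level. The percentile describes these libraries and is no p-value. The named genes were the delivered factors, the 10 largest rises and falls among genes at 5 RPKM or more in the higher group, up to 3 risen and 3 fallen genes of each list, and Dlx3, Lhx5, Nanog, Gata4, Gata6 and Sox17. Predicted genes without a symbol of their own were counted and left unnamed, and some genes that the rule names are not reported here. Largest changes among protein-coding genes alone and on the exon-length scale were added to that rule after the data were examined.

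Counting intervals on folds are 95% Clopper-Pearson intervals on the recovered reads of the groups compared. Reads amplified by PCR are not independent molecules, so these intervals and the floor of 3 reads per group, used for genes without reads, cover counting error only and are too narrow. Simulated counting noise alone put 2, 3 and 2 genes past the rule in the 3 comparisons. The procedure was tested on simulated data with changes planted at known sizes.

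Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5 RPKM, a filter at 5 RPKM and none, a rule of 2, centring on the median and scaling by a trimmed mean (30% of ratios and 5% of levels). After the data were examined, values rescaled to exon length, protein-coding genes alone, a minimum of 100 reads, removal of the trend with transcript GC in 20 bins (for genes with a GC value), and comparisons without the SKM library were added. Comparisons without SKM set columns of different tables side by side, which share 1 scale as far as the identical SKM columns show. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and plots matplotlib 3.10.9.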

Results

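RNA was sequenced from mouse embryonic fibroblasts of the skin that had been infected with doxycycline-inducible lentivirus. The 4 groups received an empty vector, SKM (SOX2, KLF4 and c-MYC), OSKM (the same factors with OCT4) or G3SKM (the same factors with GATA3). Each group had 1 value per gene, which stood for 2 replicates combined, so no spread between replicates can be set against any difference given here. The depth recovered from the values was 111 M reads (mega-reads) for empty vector, 54.0 M for SKM, 74.7 M for OSKM and 102 M for G3SKM. At 1 RPKM (reads per kilobase of gene, scaled to depth) or more there were 8984 genes in empty vector, 9324 in SKM, 9633 in OSKM and 9741 in G3SKM. A gene was called higher or lower by a fixed rule of size, an absolute log2 ratio of at least 1 after 1 RPKM was added to both values, with no test. Folds are ratios of the RPKM themselves, and the bounds in brackets are 95% Clopper-Pearson intervals, which cover counting error only.

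Of the delivered factors, Sox2 was at 0.260 RPKM in empty vector, 187 in SKM, 110.5 in OSKM and 70.7 in G3SKM. Klf4 was at 6.26 RPKM in empty vector, 19.3 in SKM, 13.9 in OSKM and 8.55 in G3SKM. Myc was highest in the cells without delivered factors, at 16.0 RPKM against 11.9 in SKM, 10.53 in OSKM and 6.31 in G3SKM. Pou5f1, the gene of OCT4, was listed at 0 in empty vector and stood at 0.297 RPKM in SKM, 3.69 in OSKM and 0.212 in G3SKM. Gata3 was at 0.0639 RPKM in empty vector, 0.0444 in SKM, 0.0836 in OSKM and 0.571 in G3SKM. In groups that received a factor, its value may combine delivered and endogenous transcripts, which the values per gene do not separate.

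**Figure D1:**
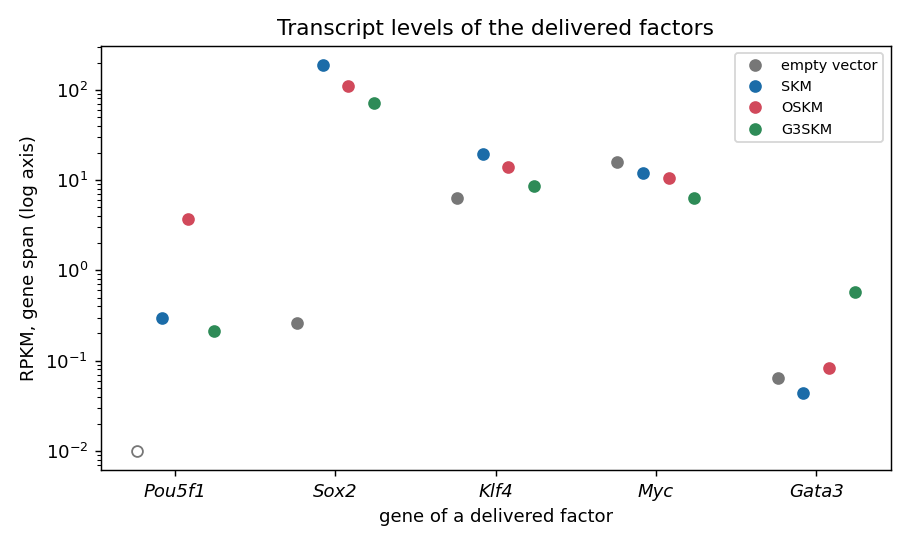
Level of the 5 delivered factors in RPKM (log axis) in the 4 groups, 1 value per group. The open symbol at 0.01 marks Pou5f1 in empty vector, listed at 0, and Pou5f1 and Gata3 peak in the groups that received them, at 3.69 and 0.571 RPKM.

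The SKM library differed from the other 3 in how its values followed the GC content of the transcripts. Across genes, Spearman's rho between the log2 ratio and transcript GC was 0.496 for SKM against empty vector, -0.708 for OSKM against SKM and -0.715 for G3SKM against SKM. Between libraries other than SKM it was 0.0597 for OSKM against empty vector, -0.00225 for G3SKM against empty vector and 0.0558 for OSKM against G3SKM. Genes are not independent replicates in these correlations. All 3 deposited comparisons contain the SKM library, so the main counts and list medians are also given after removal of this trend, within or at the end of each comparison.

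**Figure D2:**
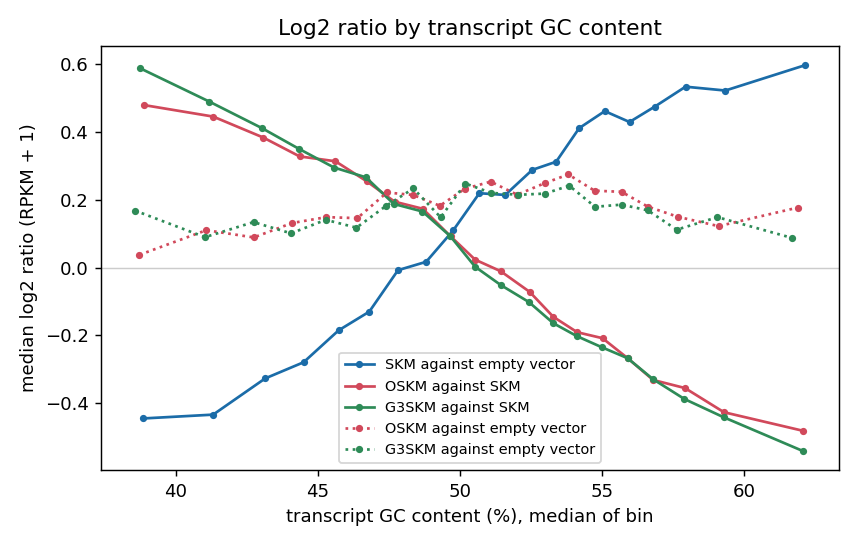
Median log2 ratio in 20 bins of transcript GC content (percent) for each pair of libraries except OSKM against G3SKM, which is not plotted. SKM against empty vector slopes from -0.44 to 0.60, OSKM against SKM from 0.48 to -0.48 and G3SKM against SKM from 0.59 to -0.54. The plotted pairs without SKM stay within 0.04 to 0.27 for OSKM against empty vector and 0.09 to 0.25 for G3SKM against empty vector.

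SKM against empty vector compares cells given the 3 factors that both other sets share with cells given none. In SKM 6 of 6 measured keratinocyte genes (13 on the list) and 3 of 7 epithelial genes were higher by the rule of size. Lower were 9 of 26 fibroblast matrix genes, 5 of 13 mesenchymal regulators and 7 of 8 macrophage genes. Krt14, a keratin of basal epidermal cells, was at 33.8 RPKM against 0.0656, 515-fold higher (364 to 753). Cldn3, a tight junction protein, was 109-fold higher (74.2 to 168). Ptgs2, the inducible cyclooxygenase, fell from 47.4 to 1.59 RPKM, 29.8-fold lower (27.6 to 32.1), and Ccn2, a matricellular growth factor, fell from 827.5 to 103 RPKM, 8.03-fold lower (7.91 to 8.15).

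By the rule of size, 905 genes were higher and 610 lower of 10195 compared. Besides Sox2, with a log2 ratio of 7.22, the largest rises on the deposited scale among genes with a name were in Bglap2 (5.71), which encodes an osteocalcin, in Bex1 (5.14), Krt14 (5.03), Krt16 (4.97), Bglap (4.86), Slurp1 (4.68), Bex4 (4.65), Phlda2 (4.34) and Cldn3 (4.17). The ranking depends on the scale, and on exon length Fetub (5.95), Krt90 (5.78) and Nat8f3 (5.42) were also among the largest rises. Slurp1 had no reads in empty vector and was at least 3391-fold higher against a floor of 3 reads. Krt16 was at 30.6 RPKM against 0.00940, a ratio that rests on a few reads in empty vector (3253-fold, 1089 to 15450). Bglap2 was 661-fold higher (348 to 1447), and reads shared between Bglap2 and its close relative Bglap were not examined. Besides Ptgs2 (-4.22) and Ccn2 (-2.99), the largest falls included those of the platelet chemokine gene Pf4 (-3.73), Lyz2 (-2.88), the protease gene Plau (-2.86), Ankrd1 (-2.83), the growth factor gene Hbegf (-2.75), Htr1b (-2.66) and Igfbp5 (-2.62).

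Of the fixed gene lists, 14 had at least 5 measured members, and 8 of these had a median outside the central 95% of random lists matched on level. The keratinocyte list had 6 of 6 measured members higher, with a median log2 ratio of 1.91 and a percentile of 100. Of its 13 genes only these 6 passed the filter, which a gene can pass by its SKM level alone. On the exon-length scale 7 were at 1 RPKM or more in SKM and 3 in empty vector. Krt14, Krt17 (3.55) and Krt6a (2.56) led the keratinocyte list, and Perp (1.26) is also on the p53 list. The epithelial list had 3 of 7 measured members higher and 4 under the rule, with a median of 0.99 at percentile 99.6. Cldn3 and Krt8 (3.47), a keratin of simple epithelia, rose most, followed by Cldn4 (1.44). Cdh1, the gene of E-cadherin, named after its values were seen, stayed under the filter at 0.284 RPKM against 0.000807, 351-fold higher (161 to 959.5). Rescaled to exon length, the epithelial list had 11 of 12 measured members higher, with a median of 1.71.

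Genes of the nucleolus and of MYC targets had 8 of 20 members higher and 12 under the rule, with a median of 0.82 at percentile 99.99. Srm, which makes spermidine, rose by a log2 ratio of 1.74, Rrp9, a factor of ribosomal RNA processing, by 1.61, and Cad, an enzyme of pyrimidine synthesis, by 1.45. In glycolysis 2 of 16 genes were higher, Pfkl (1.32) and Slc16a3 (1.03), with a list median of 0.59 at percentile 99.6. After removal of the GC trend the median was 0.28 at percentile 88.5, inside the central range, and no member passed. On the exon-length scale it was 0.68 at percentile 99.7, with 5 of 18 higher. With exon length and GC removal together it was 0.43 at percentile 98.4, with 2 of 18 higher, so the result depends on the scale.

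The fibroblast matrix list had 9 of 26 measured members lower, 17 under the rule and none higher, with a median of -0.73 at percentile 0. Tagln, an actin-binding protein of contractile cells, stood at -1.67, Lox, which crosslinks collagen, at -1.57 and Fbln2 at -1.54. Of the mesenchymal regulators, 5 of 13 were lower and 8 under the rule, with a median of -0.83. Snai2, a repressor of epithelial genes, was at -1.83, fibronectin (Fn1) at -1.47 and Prrx1 at -1.34. The macrophage list had 7 of 8 measured members lower, with a median of -1.34 at percentile 0. Lyz2, the lysozyme of myeloid cells, was 12.0-fold lower (10.8 to 13.4), C1qa, a complement subunit, 29.1-fold lower (19.5 to 45.6) and C1qc 7.61-fold lower (5.995 to 9.80).

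Imprinted genes went in both directions, with 3 of 15 higher, 1 lower and a median of -0.32 at percentile 2.04. After removal of the GC trend the median was -0.17 at percentile 4.275, inside the central range. With exon length and GC removal together it was -0.37 at percentile 1.12, outside it. Phlda2 (4.34), which restrains placental growth, Nnat (1.87) and Peg12 (1.14) were higher, and Igf2, a fetal growth factor, fell by 1.55 on the log2 scale. Genes of p53 and senescence were split as well, with 3 of 17 higher and 3 lower and a median of 0.06 at percentile 36.7. Bbc3 (1.34), Perp (1.26) and Cdkn2a (1.10) were higher, and Plk2 (-2.42) and Ccng1 (-1.14) were among the lower ones. The cell cycle list had 1 of 26 members higher, the replication helicase gene Mcm7 (1.01), with a median of -0.04 at percentile 12.0. Of the interferon response genes 1 of 9 was higher, Bst2 (1.02), with a median of -0.21 at percentile 10.8. Of the Hox genes 2 of 21 were higher, Hoxd13 (1.54) and Hoxd9 (1.32), with a median of 0.19 at percentile 64.4.

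Among lineage genes, the ectoderm list had 3 of 10 members higher and 1 lower, with a median of 0.36 at percentile 79.9. Sox3 (3.83) and the neural factor gene Neurog2 (1.09) were among the higher ones, and Nes (-1.66) was lower. Sox3 reads came to 7.11% of Sox2 reads in SKM, 7.39% in OSKM and 6.16% in G3SKM, and there were 0 Sox3 reads in empty vector. Reads shared between Sox3 and the delivered Sox2 were not examined, so the Sox3 values may not reflect Sox3 itself. Dlx3 was at 0.466 RPKM against 0.0173 (26.9-fold, 14.1 to 57.1) and Lhx5 at 0.0387 against 0.00188 (20.6-fold, 4.996 to 182), both under the filter. The mesendoderm list had 1 of 5 members higher, Hand1 (2.65), and a median of 0.02 at percentile 40.3. Gata6 was at 0.213 RPKM against 0.247, Gata4 at 0.00737 against 0.00235, and Sox17 was not listed in this table. Of the pluripotency genes 2 of 4 measured were higher, Zfp296 (1.64) and Mybl2 (1.20), and Nanog was at 0.0906 RPKM against 0.0340. Trophoblast genes Esx1 (1.95) and Peg10 (1.15) were higher among 3 measured. Of the markers of other cell types, no endothelial and no erythroid gene reached the filter, Actc1 (-1.03) was lower among 3 skeletal muscle genes, Bglap was higher and Spp1 (-1.56) lower among 3 genes of cartilage and bone, and neither the 2 adipocyte genes nor the 1 Schwann cell gene measured passed the rule.

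The median log2 ratio of all genes was 0.15, and centred on it the counts turned to 608 higher and 843 lower. Among genes with a GC value 824 were higher and 543 lower, and after removal of the GC trend 568 and 402. The keratinocyte list then had 4 of 6 higher (median 1.85), the epithelial list 4 of 7 (1.03) and the nucleolar and MYC-associated list 6 of 20 (0.77). The fibroblast matrix list had 7 of 26 lower (-0.89), the mesenchymal regulators 5 of 13 (-0.78) and the macrophage list 7 of 8 (-1.69). The medians of the mesendoderm and cell cycle lists, both inside the central range, turned to -0.24 and 0.04, and Mybl2, Prrx1, Neurog2, Mcm7, Bbc3, Cdkn2a, Ccng1, Bst2, Pfkl, Slc16a3, Hoxd9 and Peg12 were under the rule.

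**Figure D3:**
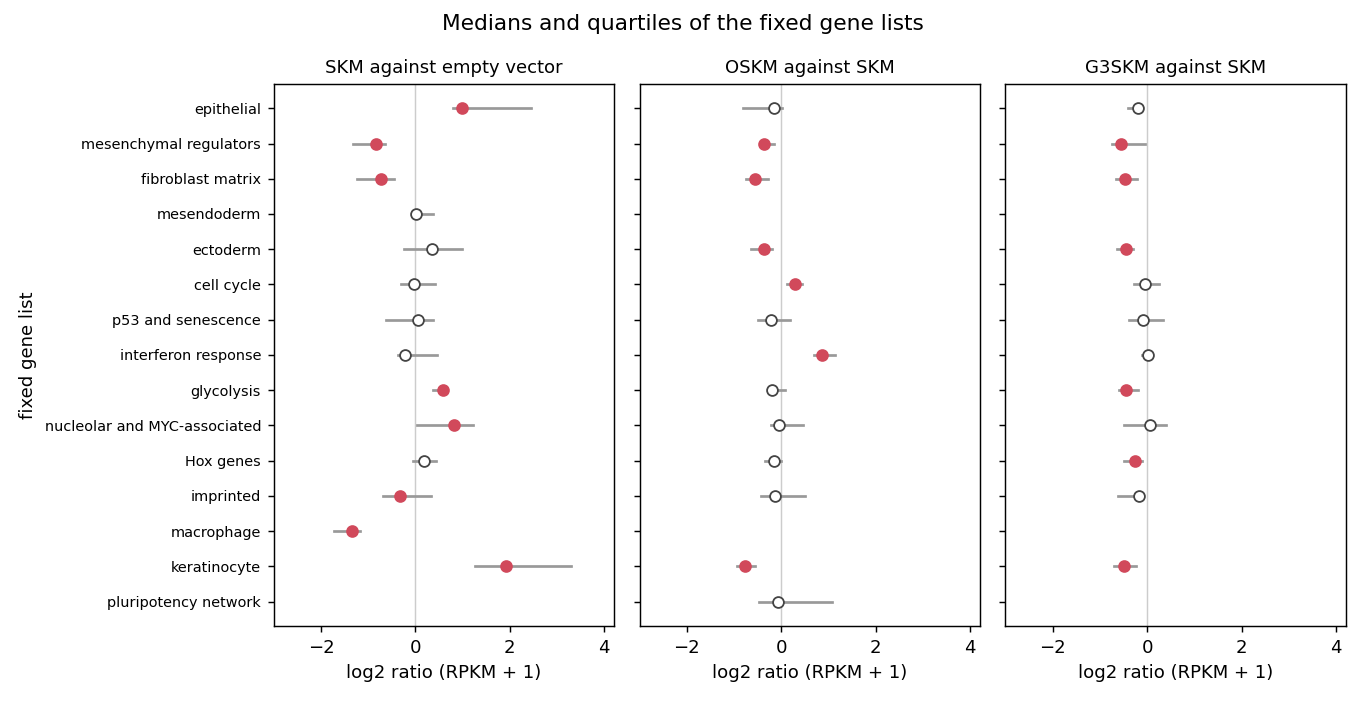
Median log2 ratio of each fixed gene list with at least 5 measured members in the 3 comparisons, with 1 value per group. In SKM against empty vector the keratinocyte list stood highest at 1.91 and the macrophage list lowest at -1.34, and in OSKM against SKM the interferon response list stood highest at 0.86.

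OSKM against SKM compares cells with and without OCT4 beside the other 3 factors. Sox2, Klf4 and Myc were also lower in OSKM than in SKM, though none by the rule. An effect of OCT4 therefore cannot be told apart from one of their lower levels. The size of this difference depends on the GC trend of SKM. The median of the 4 measured delivered factors, Pou5f1 included, moved from -0.31 to -0.14 after its removal. With exon length as well it was -0.05. With OCT4, 5 of 15 measured interferon response genes (26 on the list) and 3 of 7 pluripotency genes (33 on the list) were higher by the rule. Sprr1a, Sbsn, Cdsn, Cldn3 and Col1a1 were lower. Oasl2, which is induced by interferon, was at 7.32 RPKM against 0.994, 7.37-fold higher (6.86 to 7.93), and Isg15, a ubiquitin-like modifier, was 3.38-fold higher (3.16 to 3.62). Fgf4, a growth factor of the early embryo, was 60.02-fold higher (37.4 to 97.6) at 1.15 RPKM. Sprr1a, a protein of the cornified envelope, was 5.11-fold lower (4.63 to 5.65).

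Of 10211 genes, 260 were higher and 167 lower. Among them 128 of the higher and 11 of the lower genes were pseudogenes, while 67 protein-coding genes were higher and 83 lower. Rescaled to exon length, 386 protein-coding genes were higher and 206 lower, so the balance among them depends on the scale. Among genes with a GC value 234 were higher and 146 lower on the deposited scale. After removal of the GC trend 101 genes were higher and 98 lower, or 326 and 168 on the exon-length scale. The pseudogenes among the 101 and 98 came to 38 and 5. On the deposited scale, the largest rises among protein-coding genes after Oasl2 (2.06) and Isg15 (1.68) were in Rtp4 (1.5), Nrarp (1.48), a Notch target, the water channel gene Aqp3 (1.47) and the ribosomal protein gene Rpl22l1 (1.40). Pou5f1 itself was 12.4-fold higher (9.90 to 16.0), with a log2 ratio of 1.86. The largest falls included Mir25 (-2.46), Sprr1a (-2.07), Cldn3 (-1.90), Sbsn (-1.84), the transcription factor gene Cebpb (-1.75), Crct1 (-1.60), the skin protease gene Asprv1 (-1.57), Cdsn (-1.57), which encodes corneodesmosin, and Psca (-1.40).

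Among the fixed lists, 6 of 13 had a median outside the central 95% of random lists. The interferon response list had 5 of 15 measured members higher and 10 under the rule, with a median of 0.86 at percentile 100. After Oasl2, Isg15 and Rtp4, the others were Gbp3 (1.18) and Irf7 (1.11), both named after their values were seen. Rescaled to exon length, 15 of 23 members were higher with a median of 1.09, and after removal of the GC trend the median was 0.86 with 4 of 15 higher. The cell cycle list had no member past the rule, yet its median of 0.29 stood at percentile 99.8.

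Pluripotency genes had 3 of 7 measured members higher and 4 under the rule, with a median of -0.08 at percentile 28.3. The median was 0.46 at percentile 96.4 on the exon-length scale, with 5 of 11 higher, and 0.18 at percentile 96.3 after removal of the GC trend. With both it was 0.30 at percentile 98.1, so the direction of the list is left open. The 3 were L1td1 (1.39), 10.3-fold higher (8.63 to 12.4), Fgf4 (1.08) and Nr0b1 (1.07), which had no reads in SKM and was at least 82.7-fold higher. Nanog was at 0.137 RPKM against 0.0906, a difference whose interval includes no change (1.51-fold, 0.995 to 2.33). Sox17 had 14 reads in OSKM, at 0.0293 RPKM, and none in SKM.

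The fibroblast matrix list had a median of -0.55 at percentile 0, with 1 of 26 members lower, the collagen gene Col1a1 (-1.29). The keratinocyte list had a median of -0.77 at percentile 0.0250 with none of 6 past the rule, and Krt14 stood at -0.99. Of the mesenchymal regulators 1 of 11 was lower, Snai1 (-1.19), and the median was -0.37 at percentile 1.3, or -0.09 and inside the central range on the exon-length scale. The ectoderm list had a median of -0.37 at percentile 0.890. It moved inside the central range after removal of the GC trend (-0.11, percentile 13.9) and on the exon-length scale (-0.20, percentile 7.84). Dlx3 was at 0.118 RPKM against 0.466, a ratio of 0.254 (0.179 to 0.361), and Lhx5 at 0.0182 against 0.0387, a ratio of 0.470 (0.215 to 0.993). Glycolysis genes had a median of -0.19 at percentile 4.11 with none of 16 past the rule, and the median turned to 0.04 at percentile 57.4 after removal of the GC trend. The epithelial list had 1 of 8 lower, Cldn3, and a median of -0.16 at percentile 15.1. With exon length and GC removal together the epithelial median turned to 0.19 at percentile 91.7. Imprinted Meg3 (-1.32) and Dlk1 (-1.27) were lower, 2 of 16, with a median of -0.14. Ccng1 (1.09) was the 1 of 17 p53 and senescence genes higher, with a median of -0.21 at percentile 10.2, or 0.05 at percentile 55.1 on the exon-length scale.

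Neither the 21 Hox genes, with a median of -0.16 at percentile 5.22, nor the 20 nucleolar and MYC-associated genes, with a median of -0.05 at percentile 41.4, had a member past the rule. None of 3 macrophage, 4 mesendoderm, 3 trophoblast, 2 skeletal muscle, 2 adipocyte, 1 Schwann cell and 1 erythroid genes passed either, and Bglap (-1.14) was lower among 3 genes of cartilage and bone. Gata6 was at 0.166 RPKM against 0.213 and Gata4 at 0.00460 against 0.00737. After removal of the GC trend the medians were -0.40 for the fibroblast matrix, -0.47 for the keratinocyte, -0.20 for the mesenchymal regulator and 0.20 for the cell cycle list, all still outside the central range. The Hox genes moved outside it, with -0.14 at percentile 2.27 and 1 of 21 lower, and the imprinted median turned to 0.03 at percentile 65.3. Snai1, Col1a1, Ccng1 and Bglap were then under the rule.

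G3SKM against SKM compares cells with and without GATA3, in place of OCT4, beside the same 3 factors. Sox2, Klf4 and Myc were also lower in G3SKM than in SKM. An effect of GATA3 therefore cannot be told apart from one of their lower levels. Gata3 itself was 12.9-fold higher (10.3 to 16.3), with a log2 ratio of 0.59 that stayed under the rule because its level was below 1 RPKM. On the exon-length scale Gata3 passed the rule, as the 1 of 4 measured delivered factors higher. Of the small nucleolar RNAs 86 of 202 were higher and 1 lower, of the processed pseudogenes 187 of 1619 were higher and 28 lower, and Sox2, Klf4, Cldn3 and Col1a1 were lower. Rpl22l1, a ribosomal protein paralog, was at 50.5 RPKM against 9.57, 5.28-fold higher (4.95 to 5.63), and Rpl39 was 3.71-fold higher (3.60 to 3.83). Sox2 was 2.64-fold lower (2.59 to 2.70) and Cldn3 3.39-fold lower (3.10 to 3.71).

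Of 10214 genes, 452 were higher and 112 lower. Among the 9460 with a GC value 374 were higher and 97 lower, and after removal of the GC trend 186 and 57. The higher genes included 50 protein-coding genes and the lower ones 36, or 235 and 68 on the exon-length scale. Most small nucleolar RNAs and processed pseudogenes did not pass the rule. With the GC trend removed, 52 of 202 small nucleolar RNAs were higher and 2 lower, 82 of 1619 processed pseudogenes were higher and 14 lower, and 20 protein-coding genes were higher and 22 lower. Of 528 genes with less than 300 bases of exon, 159 were higher and 22 lower. Rnu2-10, a gene of the U2 spliceosomal RNA, rose most among named genes (2.78). On the deposited scale, of the protein-coding genes Rpl22l1 (2.28), Rpl39 (1.86), Gnb1l (1.81), Rps27a (1.80), Ly6a (1.55), the peroxiredoxin gene Prdx1 (1.47), Tmsb4x (1.45), which encodes thymosin beta-4, and the splicing gene Snrpe (1.43) rose most. The largest falls included Rpl23a-ps1 (-1.86), Mir25 (-1.71), Mir675 (-1.68), Cldn3 (-1.61), Sox3 (-1.42), Rpl28 (-1.40), Sox2 (-1.39), the linker histone gene H1fx (-1.38), Scand1 (-1.34), Sprr1a (-1.28), Cebpb (-1.25) and Gapdh (-1.23). Of 186 higher pseudogenes with a value for the most similar protein-coding gene, 55 had that gene higher by the rule on the exon-length scale. Of all 11876 protein-coding genes on that scale 235 were higher. The 186 had 114 different such genes, so some count more than once.

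Of 12 lists, 6 had a median below the central 95% of random lists and none above it. The fibroblast matrix list had 2 of 24 members lower, Col1a1 (-1.08) and Loxl1 (-1.03), with a median of -0.48 at percentile 0. Of the mesenchymal regulators 1 of 11 was lower, Foxc2 (-1.0), with a median of -0.56, or -0.16 and inside the central range on the exon-length scale. In glycolysis Gapdh was the 1 of 16 lower, with a median of -0.45 at percentile 0.03. The ectoderm list had 1 of 10 lower, Sox3, with a median of -0.45 at percentile 0.0950. Reads shared between Sox3 and Sox2, itself lower, were not examined. Dlx3 was at 0.0813 RPKM against 0.466, a ratio of 0.175 (0.122 to 0.250), and Lhx5 at 0.00206 against 0.0387, a ratio of 0.0532 (0.00603 to 0.219). None of 21 Hox genes passed, with a median of -0.26 at percentile 0.545. Of the keratinocyte list 1 of 6 was lower, Krt17 (-1.01), with a median of -0.49 at percentile 2.24. After removal of the GC trend that median was -0.11, inside the central range.

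Of 26 interferon response genes 9 were measured, against 15 in OSKM against SKM. None of the 9 passed the rule, with a median of 0.01 at percentile 52.9. The same held for the cell cycle list, with none of 26 and a median of -0.05 at percentile 63.0, and for the nucleolar and MYC-associated list, with none of 20 and a median of 0.07 at percentile 75.6. No p53 gene of 17 and no imprinted gene of 14 passed, with medians of -0.09 and -0.17. After removal of the GC trend the p53 median turned to 0.06 at percentile 80.4, and the imprinted median was -0.28 at percentile 0.3, outside the central range. Of the epithelial list 1 of 7 was lower, Cldn3, and the median was -0.19 at percentile 15.9. None of the 4 pluripotency, 4 mesendoderm, 3 trophoblast, 3 macrophage, 2 skeletal muscle, 3 cartilage and bone, 2 adipocyte, 1 Schwann cell and 1 erythroid genes measured passed the rule. Nanog was at 0.131 RPKM against 0.0906 (1.45-fold, 0.971 to 2.19), Gata6 at 0.143 against 0.213 and Gata4 at 0.00866 against 0.00737. With the GC trend removed the medians were -0.36 for the fibroblast matrix, -0.44 for the mesenchymal regulator, -0.22 for the glycolysis, -0.21 for the ectoderm and -0.24 for the Hox list, all still below the central range. The epithelial median turned to 0.01 and the nucleolar and MYC-associated median to -0.03, both inside it, and Klf4, Sox3, Snrpe, H1fx, Scand1, Cebpb, Foxc2, Col1a1, Loxl1 and Krt17 were under the rule.

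OSKM and G3SKM were each compared with the same SKM library, so variation of that sample moves both ratios alike and their calls are not independent. Of 9899 genes compared in both, 133 were higher in both and 32 lower in both, and none moved in opposite directions past the rule. Independent calls would give 9.47 and 1.89, which does not allow for the shared SKM library. Rpl22l1 and Rpl39 were among the genes higher in both, and Cldn3, Sprr1a, Cebpb and Col1a1 among those lower in both. The interferon genes Oasl2, Isg15 and Rtp4, higher in OSKM, were at log2 ratios of 0.10, -0.05 and 0.18 in G3SKM, and Oasl2 was 6.41-fold higher in OSKM than in G3SKM (6.09 to 6.75). Across genes, Pearson's r between the log2 ratios was 0.72 and Spearman's rho 0.75. Both ratios contain the SKM library, so simulated counting noise without any change gave an r of 0.66, and r alone shows no shared change. The covariance was 0.18, against 0.00402 from that noise, which put 1 gene past the rule in the same direction. Among 9185 genes with a GC value, 33 were higher in both and 16 lower in both after removal of the GC trend. Independent calls would give 1.39 and 0.608. The r of these genes was then 0.52, against 0.65 from noise, and again r alone shows no shared change. Their covariance was 0.0695, against 0.00384 from noise, which put 0 genes past the rule in the same direction. Simulated noise covers counting alone. Any other variation of the SKM sample enters both ratios as well, so how much of the overlap is shared by OSKM and G3SKM themselves is left open.

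**Figure D4:**
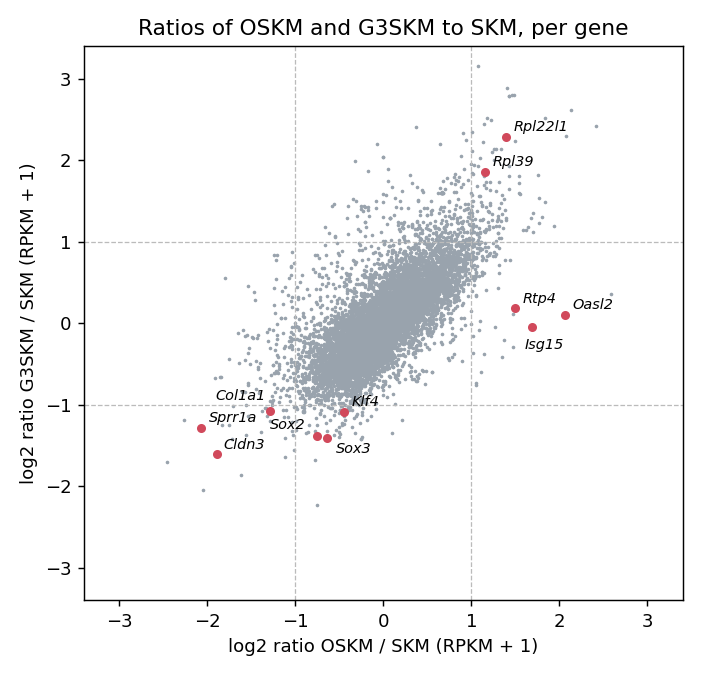
Log2 ratio of OSKM to SKM (x axis) and of G3SKM to SKM (y axis) for each gene at 1 RPKM or more in both comparisons, 1 point per gene, with dashed lines at the rule of size. Oasl2, Isg15 and Rtp4 lie to the right near 0 on the y axis, and Cldn3 lies low on both, at -1.90 and -1.61.

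Genes past the rule in SKM against empty vector were also counted by their direction in OSKM and G3SKM. The SKM value enters these ratios with opposite signs, so variation of the SKM sample alone moves genes back toward empty vector. The shares of all genes given beside the counts do not allow for this. Of the 905 genes higher in SKM, 101 (11.2%) were lower in OSKM, against 1.71% of all genes, and 56 (6.19%) were lower in G3SKM, against 1.15%. Cldn3 was among them in both. Of 540 genes lower in SKM, 128 (23.7%) were higher in OSKM, and of 548 lower in SKM, 146 (26.6%) were higher in G3SKM, against 2.32% and 4.25% of all genes. Ccng1 was 1 of those higher in OSKM. After removal of the GC trend the numbers were 62 of 568 and 37 of 568 for the higher genes and 24 of 345 and 45 of 350 for the lower genes. The genes higher in SKM then had a median of -0.35 in OSKM, with 83.6% moving down at any size, and -0.21 in G3SKM, with 71.5%. The genes lower in SKM had medians of 0.04 and 0.10, with 54.8% and 58.6% moving up. How much of this is an effect of OCT4 or GATA3, or of the lower Sox2, Klf4 and Myc levels in both groups, is left open.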

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

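Of the alternatives given here, those chosen only after the data were seen are exon length, protein-coding genes alone, a minimum of reads, removal of the GC trend, and their combinations. No paired analysis was possible because each group has only 1 value, and alternatives fixed beforehand that need the authors' FDR or values per replicate (replicates left out, a replicate block, another counting model) were not run. Counts of changed genes follow in the order SKM against empty vector, OSKM against SKM and G3SKM against SKM, from 1515, 427 and 564 as reported. A pseudocount of 0.1 RPKM gave 2749, 1042 and 1095 genes, and 5 RPKM gave 468, 94 and 248. A rule of 2 left 148, 9 and 35, by its own construction. Exon length gave 2812 genes for SKM and 888 for OSKM, protein-coding genes alone 908, 150 and 86, and both together 303 for G3SKM. Removal of the GC trend left 970, 199 and 243, among genes with a GC value only. A filter at 5 RPKM left 284 for OSKM and 3, 3 and 3 lists outside the central range, from 8, 6 and 6, with fewer lists large enough. That filter also turned the imprinted list in SKM against empty vector to 0.12. With exon length and GC removal together, the ectoderm list in OSKM against SKM turned to 0.0802 and the keratinocyte list in G3SKM against SKM to 0.0339. Genes past the rule in the same direction in OSKM and G3SKM numbered 414 with a pseudocount of 0.1, 4 with a rule of 2, 49 after GC removal and 99 with exon length and GC removal, from 165. The return of SKM changes in OSKM and G3SKM covered 987, 13 and 168 genes with the same pseudocount, rule and GC removal, from 431. Beyond what a stricter rule or fewer genes give by construction, the cause was not tested. Named genes past the rule kept their direction under every alternative run. Of those called, 52 with a pseudocount of 5, 30 after GC removal, 7 after centring and 6 after trimmed-mean scaling were no longer past the rule. Of the lists outside the central range, 4 moved inside it after GC removal, 4 with exon length, 3 with the stricter filter, the imprinted list included, and 1 with trimmed-mean scaling. Moving outside it were 2 after GC removal (Hox genes in OSKM, imprinted genes in G3SKM) and 2 with exon length (interferon response in SKM, Hox genes in OSKM), and with both together 5 moved inside and 2 outside. Leaving out the filter cannot move a call, since 1 RPKM is added to both values. On simulated data, changes of 3-fold were called in 82% to 86% of genes and 2-fold changes in 4% to 12%. As 1 RPKM is added to both values, a 2-fold change passes the rule only through counting noise. For the same reason genes at low level are under-called by construction, and no changes were simulated in them.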

Other observations

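The tests with Krt5 and with GC content as the whole cause of the excess, and all comparisons without the SKM library, were chosen after the results were seen. Set against empty vector without the SKM library, OSKM had 492 genes higher and 425 lower of 10212, and G3SKM 732 higher and 386 lower of 10298. The fibroblast matrix list had 17 of 28 members lower in OSKM (median -1.20) and 18 of 26 lower in G3SKM (median -1.16), and the mesenchymal regulators 8 of 13 and 9 of 13. The keratinocyte list had 4 of 5 members higher in both, with medians of 1.91 and 2.38, and 7 of 8 macrophage genes were lower in both, with medians of -1.51 and -1.44. Pluripotency genes had 5 of 7 members higher and 1 lower in OSKM, with a median of 1.11, and 1 of 4 higher and 1 lower in G3SKM, with a median of 0.31. Nucleolar and MYC-associated genes had 5 of 20 higher in OSKM and 3 of 20 in G3SKM.

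OSKM set directly against G3SKM had 74 genes higher and 230 lower of 10222, or 227 higher and 287 lower on the exon-length scale. Of the interferon response list 5 of 15 were higher in OSKM, with a median of 0.83 at percentile 100, led by Oasl2, 6.41-fold higher (6.09 to 6.75). Nr0b1 was 233-fold higher in OSKM (64.0 to 1932), Fgf4 28.2-fold (22.4 to 36.2) and L1td1 11.7-fold (10.2 to 13.5). The chemokine genes Cxcl1 (-1.75), Cxcl5 (-1.63), Ccl7 (-1.49) and Ccl2 (-1.43) were lower in OSKM, and the transcription factor genes Pou3f4 (1.81) and Foxd1 (1.76) higher, all chosen after their values were seen. Of 202 small nucleolar RNAs, 113 were lower in OSKM than in G3SKM and 1 higher. Against empty vector, 135 of 200 were higher and 1 lower in G3SKM, 46 of 173 higher and 12 lower in SKM, and 14 of 165 higher and 5 lower in OSKM. With the GC trend removed, SKM had 59 of 173 higher and 2 lower, so higher small nucleolar RNAs were not particular to G3SKM.

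Macrophage genes were lower in SKM than in empty vector in 7 of 8 members measured, with the abundant Lyz2 at 1.37 RPKM against 16.4 and Cd68 at 1.81 against 5.05. GC content is excluded as the whole cause, since the list's median was -1.69 after removal of the GC trend. A smaller share of macrophages among the SKM cells may account for it. In another macrophage list, of 30 genes that share none with the fixed list, 16 were at 1 RPKM or more on the exon-length scale in empty vector and 2 in SKM, and the median was -0.99, close to the bound set beforehand for such a loss, with 8 of 16 measured genes lower by the rule. A smaller share and lower expression of these genes within the fibroblasts cannot be told apart in pooled cells, and an effect of the factors themselves stays untested.

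Genes of the keratinocyte list were higher in SKM than in empty vector in 6 of 6 members measured, of 13 on the list. Keratinocytes carried along with the SKM cells are argued against by Krt5, the usual partner of Krt14, which stood at 0.370% of the Krt14 level on the exon-length scale (0.312 against 84.3 RPKM), and per the labels the epidermis had been removed before culture. Of 20 keratinocyte identity genes, 6 of them shared with the fixed list, 8 were measured and 4 were higher by the rule, and 7 were at 1 RPKM or more in SKM against 4 in empty vector. GC content is excluded as the whole cause, with a median of 1.85 after removal of the GC trend. Activation of some epidermal genes within the infected cells may be proposed as a hypothesis, which was not tested. Slurp1 and Perp were also higher, so the rise was not limited to keratin genes. Reads shared among related keratins were not tested.

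More genes were higher than lower in G3SKM against SKM, 452 against 112. GC content may account for part of them, since rho between the log2 ratio and transcript GC was -0.715 and 206 of 374 higher genes with a GC value no longer passed once the trend was removed. Of the 243 genes then past the rule 76.5% were higher. On the deposited scale this excess lay in small nucleolar RNAs (52 higher, 2 lower) and processed pseudogenes (82 and 14), not in protein-coding genes (20 and 22). On the exon-length scale protein-coding genes were 235 higher and 68 lower before GC removal. After GC removal on that scale 305 genes of all classes were higher and 89 lower, not counted by class. The removal subtracts a median over all genes in each GC bin, so a different trend within 1 class of genes would stay. GC content as the whole cause is therefore not excluded by the removal. In G3SKM against empty vector, with a rho of -0.00225, 135 of 200 small nucleolar RNAs were higher and 1 lower. Processed pseudogenes were 84 higher and 26 lower there. In OSKM against G3SKM, with a rho of 0.0558, 1 small nucleolar RNA was higher and 113 lower, and 11 processed pseudogenes were higher and 6 lower. These pairs all rest on the 1 G3SKM library. Exon length gave a rho of -0.108. Of the higher pseudogenes with a value for their parent gene, 29.6% had a parent higher by the rule. Among all protein-coding genes on that scale 235 of 11876 were higher. The 186 pseudogenes had 114 different parents, so some parents count more than once. Both a gain of short RNAs in that library and reads shared with parent genes stay open. An effect of GATA3 cannot be told apart from these, or from the lower Sox2, Klf4 and Myc levels in G3SKM, with 1 library per group.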
